A study of Mus musculus with 12 samples.

How the data were processed

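RNA was sequenced from NKC cells, a mouse pancreatic ductal adenocarcinoma (PDAC) line that carries Kras G12D per the labels. The 12 samples form 4 groups of 3: a control short hairpin RNA (shctrl), a hairpin against Ezh2 (shEZH2), a CRISPR/Cas9 control (cas9ctrl) and CRISPR/Cas9 directed at Ezh2 (cas9EZH2). Per the labels' protocols, RNA was taken with Trizol and made into mRNA libraries. How the hairpin or the guide was chosen, and whether the edited cells are a clone or a pool, is not given in the sources used here.

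Per the submitters' processing notes, the reads were checked with FastQC and aligned to mm9 with TopHat2 2.1.0. The notes also name Cuffnorm 2.2.1 and Cuffdiff 2.2.1. The authors deposited a Cuffdiff gene table for each of the 2 comparisons. Each holds 24325 gene entries, of which 24324 have a partner in the other table. Per the file headers and the values, the authors' FPKM (fragments scaled to transcript length and to the mapped fragments of the library) is a single value per group and was scaled within its own table. The authors' log2 fold change is the log2 of the EZH2-depleted FPKM over the control FPKM with no pseudocount for tested entries above 0 in both groups, except for 1 entry of the knockout table (a gap of 0.16). It is set to 0 for the 2 entries of each table whose test failed and for the 1 with too many reads, and is otherwise infinite where only 1 group is listed at 0. The deposited test statistic, a score of the log2 fold change over its error, is set to 0 for entries that were not tested. The authors' p-value has a smallest value of 5e-05, and the deposited q-value is its Benjamini-Hochberg adjustment over the tested entries, within 5.25e-07 of a recomputed one. The library normalization setting, the gene annotation and the options of Cuffdiff are not given in the sources used here.

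The tables hold no value per replicate, so no standard deviation over replicates was computed. The depth of each sample is not known from them, and no interval or detection floor that needs it is given. The only error used is the one implied by the deposited score, the log2 fold change divided by the test statistic. Over the tested genes it had a median of 0.26 in the knockdown and 0.21 in the knockout. Genes called by the authors' own test (deposited q-value under 0.05) are written as rose, fell or changed. Levels set across the 2 tables were normalized separately and were not tested.

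The following choices were made before the data were examined: the groups, the tests, 30 gene lists with 1011 symbols, the rule for named genes and the alternatives of the plan. Of the list symbols, 1002 were found in the tables. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on the deposited score of tested genes. The inter-gene correlation was preset at 0.01, and adjustment ran over the lists with at least 5 members tested. Genes listed at 0 in a group have no finite score and are outside this test. An inter-gene correlation cannot be estimated without values per replicate, so each call was repeated at a preset of 0.05. The counts of members use the authors' q-value over all genes and, beside it, a Benjamini-Hochberg adjustment over the list alone. List medians are of log2 ratios with a pseudocount of 1.

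Genes called in both tables were counted per direction and compared with the product of the margins by a two-sided Fisher's exact test across genes. Genes are not independent, so its p-values describe the overlap and do not replace replicates. Spearman's rho and Pearson's r of the log2 fold changes are given across genes without a p. The difference between knockdown and knockout was tested per gene with a normal two-sided z, the difference of the 2 log2 fold changes over the root of the summed squares of their implied errors, for genes with an absolute log2 fold change of at least 0.01 in both. On data simulated for 10400 genes, this z test recovered 28% of genes made to differ by 1 log2 unit and 83% of those at 2, and called 3 unchanged genes. Noise there was normal with the same implied errors that z uses, so this run cannot check those errors. On data simulated for 11545 genes, the list test called 5 of 5 shifted lists and 0 of 20 others. The scores were shuffled over genes, which removes inter-gene correlation, so false calls that come from correlation were not probed. The overlap test on simulated independent calls gave an odds ratio of 1.04, and 2.46 with shared genes added. Those calls had a single rate per table for all genes, so power shared by genes across the tables was not probed. The list test was also run on z.

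The rule for named genes took Ezh2 and Gata6, the 10 largest rises and 10 largest falls per comparison, up to 4 called members of each list, the 5 largest shared rises and falls, the 3 largest opposite changes and the 5 largest z. It required q under 0.05 (except for z), a finite fold and at least 1 FPKM in the higher group. Any other gene is said to have been chosen after its values were seen. Coordinates are mm9 as the tables give them, 1 locus per entry, and a few entries merge several symbols (104 in the knockdown table and 105 in the knockout table). Gene groups for RNA without a poly(A) tail, for histone genes and for Y-linked genes, and all values by chromosome, were made after the tables had been seen. Medians by chromosome and in windows of 25 neighbouring genes use genes with at least 5 FPKM in a group.

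The alternatives were other thresholds, folds and adjustments, filters on low FPKM, pseudocounts of 0.1 and 1, centring, other list statistics and 10000 random lists. Alternatives added after seeing the data left out the chromosomes and RNA kinds that stand apart or changed the error or correlation of the difference tests. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tests that failed in Cuffdiff were left out: Sparc and Prrc2a in the knockdown table, Ldlr and Mon2 in the knockout table. Rn45s was left out of the knockdown tests because Cuffdiff found too many reads there.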

Results

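The series measured RNA in NKC cells, a mouse line of pancreatic ductal adenocarcinoma with Kras G12D, after depletion of EZH2 in 2 ways. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), a histone methyltransferase that keeps genes silent. The series title names an axis from EZH2 to GATA6, a transcription factor of endodermal and pancreatic development. A hairpin knockdown (shEZH2 against shctrl) and a CRISPR/Cas9 knockout (cas9EZH2 against cas9ctrl) each had their own control, with 3 samples in each of the 4 groups. Each group has a single FPKM in the authors' deposited tables, so values carry no error over replicates, and the depth of the samples is not known. The 2 tables were normalized separately, so levels set across them are a description only.

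Ezh2 transcript fell in both comparisons, and further in the knockout. EZH2 protein and histone methylation are not among the values used here, so their loss is not shown. In the authors' deposited table for the knockdown, Ezh2 (mm9 chromosome 6, 47480272 to 47545029) went from 40.4 to 28.1 FPKM, a log2 fold change of -0.52 with an implied error of 0.23 (q = 0.000708). The authors' deposited table for the knockout lists 29.0 FPKM in cas9ctrl and 7.98 in cas9EZH2, a log2 fold change of -1.86 with an implied error of 0.20 (q = 0.000439). These log2 fold changes differed from each other (adjusted p = 0.000397). Gata6 (mm9 chromosome 18, 11042034 to 11085633) rose in both, from a low level. It went from 0.737 to 2.57 FPKM in the authors' deposited table for the knockdown, 3.49-fold (q = 0.000376), and from 0.246 to 1.65 FPKM in the authors' deposited table for the knockout, 6.71-fold (q = 0.000829). The difference between these changes did not pass the test (adjusted p = 0.726). Because Gata6 is low, a pseudocount of 1 brings its log2 ratios to 1.04 and 1.09.

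The knockdown comparison asks what changes in the transcriptome of these cells with a hairpin against Ezh2. By the list test, Hox genes, p53 targets, class I antigen presentation genes and inflammatory genes lay higher than other genes, and epithelial markers and TGF-beta targets lower. Of 11656 genes tested in the authors' deposited table, 3381 changed (29.0%), 1719 up and 1662 down. At least 2-fold changes numbered 644 up and 353 down. Among the largest rises were those of Fras1 (0.0578 to 6.53 FPKM), the lipoprotein receptor gene Olr1 (0.897 to 90.5), the collagenase gene Mmp13 (0.260 to 25.2) and Pcdh17 (0.442 to 26.9), all from the authors' deposited table. The largest falls there included the basement membrane gene Nid1 (12.8 to 0.0489 FPKM), Wnt1 (19.6 to 0.142) and Wscd2 (20.6 to 0.163). Among them were also Rmrp (1744 to 9.35), Rpph1 (860 to 9.48) and Rprl3 (356 to 4.86), the RNA parts of ribonucleases MRP and P and a related small RNA. Small RNA genes whose products lack a poly(A) tail had a median log2 ratio of -4.59 over 16 genes, and 8 of 13 tested fell.

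Among the lists that lay higher in the knockdown, the Hox genes moved furthest. Of 20 tested, 13 rose and 0 fell (13 adjusted over the list alone), with a median log2 ratio of 2.12 (adjusted p = 4.47e-05, over the 12 with a finite score). Hoxb7 went from 0.937 to 9.10 FPKM, Hoxb8 from 2.2 to 8.97 and Hoxb3 from 1.88 to 6.99 in the authors' deposited table. Of the p53 targets, 17 of 29 rose and 0 fell (19 adjusted over the list alone), median 0.43 (adjusted p = 3.85e-05). They included the death receptor gene Fas (1.47 to 5.50 FPKM), Perp (157 to 496) and Pmaip1 (13.4 to 27.1). Class I antigen presentation rose in 14 of 22 members and fell in 0 (14 adjusted over the list alone), median 0.50 (adjusted p = 0.000299, and adjusted p = 0.0614 on log2 ratios). There the transactivator gene Nlrc5 went from 0.993 to 3.62 FPKM and the peptide transporter gene Tap2 from 4.80 to 11. Of the NF-kB and chemokine genes, 12 of 23 rose and 4 fell (17 adjusted over the list alone), median 0.54 (adjusted p = 0.000295), with Ccl2 up from 18 to 180 FPKM and Ccl7 from 2.73 to 77.1.

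Interferon response genes rose in 28 of 46 and fell in 5 (36 adjusted over the list alone), median 0.51 (adjusted p = 0.00136). At a correlation of 0.05 this list gave an adjusted p = 0.0651. Ifit3 went from 35.5 to 102 FPKM, whereas the antiviral synthetase genes Oas3 (9.98 to 0.242), Oas2 (5.70 to 0.217) and Oas1a (13.2 to 0.815) fell in the authors' deposited table. Growth regulators known as EZH2-repressed rose in 11 of 23 and fell in 3 (14 adjusted over the list alone), median 0.19 (adjusted p = 0.0483, and adjusted p = 0.170 at a correlation of 0.05). Among them were the WNT antagonist gene Sfrp1 (0.440 to 1.95 FPKM) and the cell cycle inhibitor gene Cdkn2a (32.6 to 106).

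Epithelial markers fell in 9 of 18 and rose in 2 (11 adjusted over the list alone), median -1.42 (adjusted p = 1.49e-10). Over the 33 members with at least 1 FPKM in a group of either table, tested or not, the median was smaller, at -0.69. The E-cadherin gene Cdh1 went from 2.01 to 0.0591 FPKM, and the claudin genes Cldn4 from 13.4 to 0.400 and Cldn3 from 124 to 7.45. These genes were far higher in cas9ctrl, in a table normalized separately, where Cdh1 was at 122 FPKM and Cldn4 at 752. TGF-beta targets fell in 15 of 26 and rose in 7 (22 adjusted over the list alone), median -0.82 (adjusted p = 3.69e-08). They included Serpine1 (203 to 33.6 FPKM), Id3 (281 to 57.1) and Id2 (202 to 43.7). Ductal markers split, with 5 of 11 up and 5 down (10 adjusted over the list alone), median -0.06 (adjusted p = 0.0231, and adjusted p = 0.0758 at a correlation of 0.05). That median lay at percentile 25 of the medians of random lists. Krt7 fell from 181 to 17.6 FPKM, and Muc1 rose from 0.404 to 2.72. NOTCH pathway genes fell in 6 of 18 and rose in 2 (9 adjusted over the list alone), median -0.09 (adjusted p = 0.0315, and adjusted p = 0.134 at a correlation of 0.05). Their median lay at percentile 22.06 of random lists. The ligand genes Jag1 (30.1 to 4.71 FPKM) and Jag2 (8.46 to 0.608) fell, and Notch3 rose (0.221 to 3.28).

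Cell cycle genes fell in 11 of 49 and rose in 1 (12 adjusted over the list alone), median -0.26 (adjusted p = 0.0140, and adjusted p = 0.158 at a correlation of 0.05). Mki67 went from 72.3 to 50.9 FPKM and Top2a from 127 to 88.4 in the authors' deposited table. Beside them, replication-dependent histone genes, whose transcripts lack a poly(A) tail, fell in 23 of 43 tested, with a median of -1.96 over 50 genes. Histone genes with a poly(A) tail had a median of -0.13. In cas9ctrl, in the table normalized separately, the replication-dependent genes had a median of 0.310 FPKM.

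The remaining lists did not pass the list test in the knockdown. Of the other PRC2 genes, Phf1 rose (8.91 to 13.9 FPKM) and Suz12 (36.0 to 25.3) and Mtf2 (11.1 to 8.56) fell among 11 (4 adjusted over the list alone), median -0.12 (adjusted p = 0.479). PRC1 genes had 2 up and 1 down of 19 (3 adjusted over the list alone), median 0.12 (adjusted p = 0.880). Developmental transcription factors outside the Hox clusters had 13 up and 9 down of 38 (23 adjusted over the list alone), median 0.07 (adjusted p = 0.749). Irx1 rose there from 0.265 to 5.36 FPKM, and Dlx2 fell from 4.68 to 0.257. Endodermal and pancreatic factors had 4 up and 7 down of 14 (12 adjusted over the list alone), median -0.42 (adjusted p = 0.520). Gata4 rose (0.440 to 5.32 FPKM), as did Foxa2 (5.53 to 14.8), and Elf3 fell (12 to 2.24). Classical subtype genes had 4 up and 3 down of 10 (8 adjusted over the list alone), median 0.31 (adjusted p = 0.973). Basal-like subtype genes had 3 up and 6 down of 12 (9 adjusted over the list alone), median -0.24 (adjusted p = 0.0620). Mesenchymal markers had 12 up and 9 down of 30 (23 adjusted over the list alone), median 0.27 (adjusted p = 0.0976), with Col3a1 up from 13.3 to 70.1 FPKM.

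RAS-ERK genes had 4 up and 13 down of 28 (20 adjusted over the list alone), median -0.32 (adjusted p = 0.0662). WNT genes had 10 up and 7 down of 23 (19 adjusted over the list alone), median 0.29 (adjusted p = 0.355). Hypoxia and glycolysis genes had 6 up and 4 down of 32 (12 adjusted over the list alone), median -0.07 (adjusted p = 0.844). ATF4 and unfolded protein genes had 13 up and 2 down of 33 (18 adjusted over the list alone), median 0.30 (adjusted p = 0.0604). Cholesterol synthesis had 1 up and 3 down of 24 (3 adjusted over the list alone), median -0.05 (adjusted p = 0.556). Ribosomal proteins had 2 up and 0 down of 54 (0 adjusted over the list alone), median 0.13 (adjusted p = 0.294). Markers of other cell types were few. Acinar markers had 0 up and 1 down of 15 (0 adjusted over the list alone), median -0.26 (adjusted p = 0.337). Endocrine markers had 1 up and 2 down of 6 (3 adjusted over the list alone), median 1.00 (adjusted p = 0.973). Fibroblast and stellate markers had 3 up and 4 down of 7 (7 adjusted over the list alone), median -0.35 (adjusted p = 0.259). Too few were tested for a list test of immune markers (0 changed of 2, 0 adjusted over the list alone, median 0.17) and endothelial markers (1 up and 1 down of 3, 2 adjusted over the list alone, median -0.02), and 0 germline genes were tested.

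Parts of the genome moved as blocks in the knockdown. Chromosome 19 genes had a median log2 fold change of 0.38 over 359 genes, with 85.5% above 0, while the medians of the other chromosomes apart from Y lay between -0.10 and 0.01. The Y-linked genes, chosen after their values were seen, fell in the authors' deposited table: Ddx3y from 19.9 to 0.727 FPKM, Uty from 6.72 to 0.239, Kdm5d from 7.03 to 0.340 and Eif2s3y from 35.2 to 2.00. Mir6236, also chosen after its value was seen, made up 47.0% of the FPKM sum of shctrl, 942891, and the sum of shEZH2 was 512239. The number of changed genes depends on the kind of p: a normal p of the centred test statistic called 1186 genes, 726 up and 460 down, and 1176 without centring, over the genes above 0 in both groups, where the authors' p called 3331. Of 111 tested genes listed at 0 in a group, 66 did not pass in the authors' deposited table, nor did genes near 0 such as Hoxa10, chosen after its values were seen, at 0.0189 and 19.2 FPKM (q = 0.386).

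**Figure D1:**
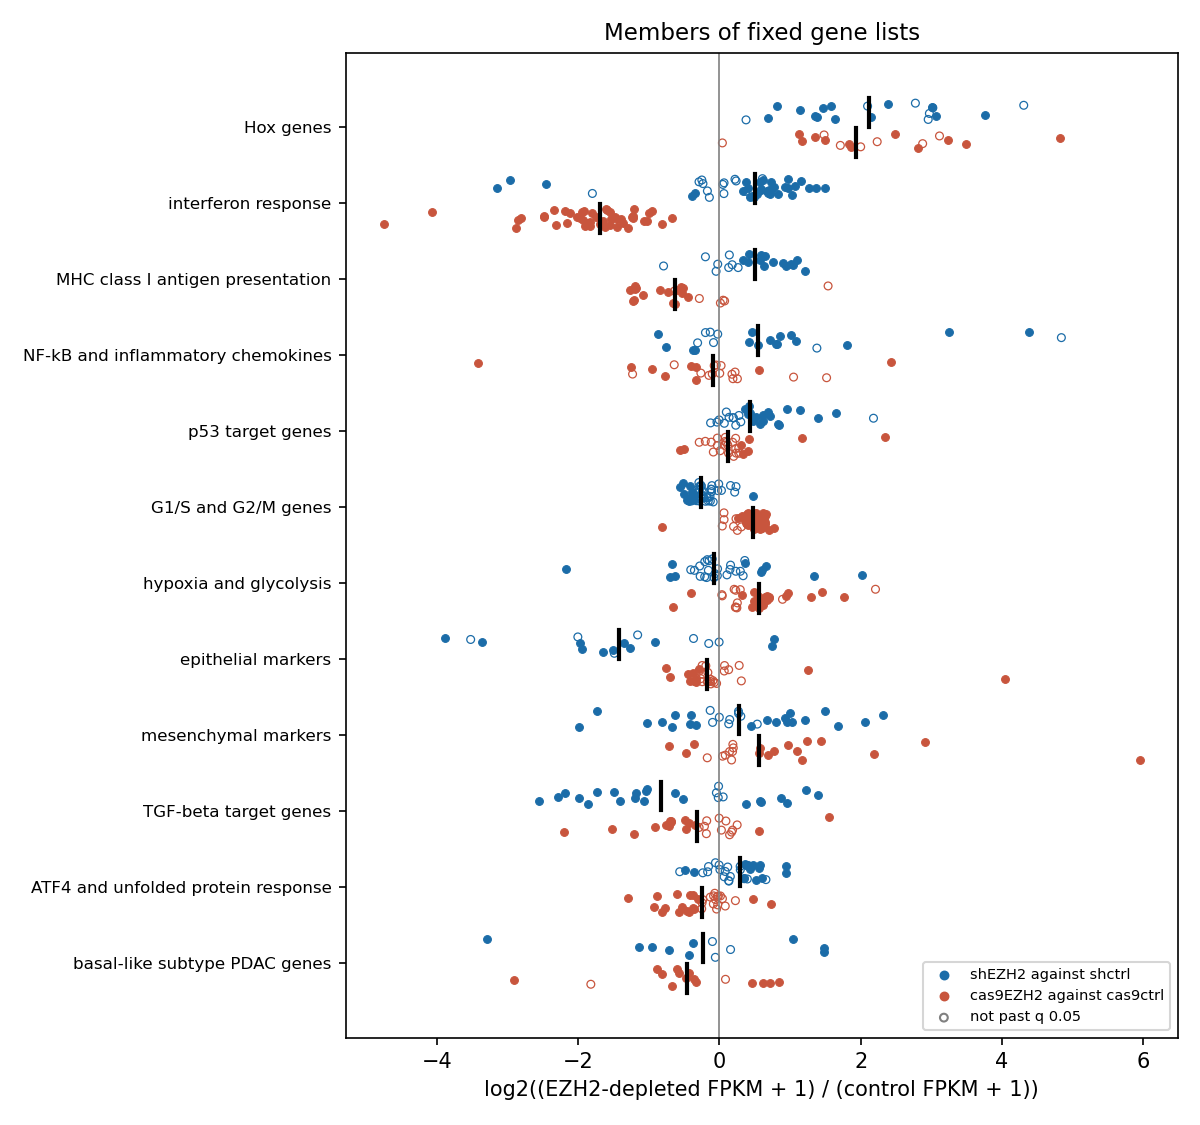
Log2 ratios with a pseudocount of 1 of the tested members of 12 gene lists in the knockdown (blue) and the knockout (red), filled where q in the authors' deposited table was under 0.05, with black bars at the medians. Hox genes lie above 0 in both, with medians of 2.12 and 1.94, and the medians of interferon genes lie on opposite sides, at 0.51 and -1.69.

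The knockout comparison asks the same of cells edited at Ezh2. Every tested interferon response gene fell, as did 16 of 22 class I antigen presentation genes, while 40 of 49 cell cycle, 20 of 33 hypoxia and 12 of 23 mesenchymal genes rose. Of 11974 genes tested in the authors' deposited table, 2851 changed (23.8%), 1449 up and 1402 down, and at least 2-fold changes numbered 462 up and 344 down. This number, too, depends on the kind of p. Over the genes above 0 in both groups, a normal p of the test statistic called 1362, where the authors' p called 2796. Among the largest rises were those of Galnt18 (0.153 to 16.5 FPKM), the RNA-binding protein gene Elavl2 (0.0534 to 4.80), the vimentin gene Vim (5.95 to 429) and Fstl1 (0.107 to 6.09). Tacstd2, an epithelial surface antigen gene, rose from 0.453 to 23. Among the largest falls in the authors' deposited table were those of the WNT antagonist gene Dkk2 (4.38 to 0.0322 FPKM), Epb4.1l3 (8.69 to 0.0880), the sialomucin gene Cd34 (33.5 to 0.586) and the claudin gene Cldn9 (104 to 1.86).

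Interferon response genes fell in 47 of 47 (47 adjusted over the list alone), median -1.69 (adjusted p = 2.75e-102). Irf7, a regulator of the response, went from 71.7 to 12.1 FPKM, Ifi44 from 66.1 to 11 and Oasl2 from 38.7 to 4.69. Oas3 (25.9 FPKM in cas9ctrl), Oas1a (15.8) and Oas2 (6.33) are listed at 0 in cas9EZH2. Class I antigen presentation fell in 16 of 22 and rose in 0 (16 adjusted over the list alone), median -0.63 (adjusted p = 6.06e-10). Its immunoproteasome genes Psmb9 (9.10 to 3.20 FPKM) and Psmb8 (6.96 to 2.48) fell. TGF-beta targets fell in 13 of 26 and rose in 2 (17 adjusted over the list alone), median -0.31 (adjusted p = 0.000295, and adjusted p = 0.13 on log2 ratios), with Id3 down from 103 to 21.6 FPKM and Id1 from 383 to 133. Basal-like subtype genes fell in 10 of 16 and rose in 4 (15 adjusted over the list alone), median -0.45 (adjusted p = 0.00365, and adjusted p = 0.108 on log2 ratios). Fgfbp1 fell there from 56.2 to 6.65 FPKM, and Sprr1a rose from 7.32 to 13.9. ATF4 and unfolded protein genes fell in 15 of 33 and rose in 2 (17 adjusted over the list alone), median -0.24 (adjusted p = 0.0190, and adjusted p = 0.137 at a correlation of 0.05). Ddit3 went from 55.9 to 29.8 FPKM in the authors' deposited table.

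Cell cycle genes rose in 40 of 49 and fell in 1 (43 adjusted over the list alone), median 0.47 (adjusted p = 3.51e-08). Bub1 went from 11.6 to 20.6 FPKM and Birc5 from 55.5 to 90.6, and E2f2 fell from 2.29 to 0.882. Hypoxia and glycolysis genes rose in 20 of 33 and fell in 2 (24 adjusted over the list alone), median 0.56 (adjusted p = 1.18e-07), with the phosphofructokinase gene Pfkp up from 15.7 to 44.5 FPKM and Bnip3 from 7.01 to 18.8. Mesenchymal markers rose in 12 of 23 and fell in 3 (15 adjusted over the list alone), median 0.56 (adjusted p = 1.07e-14). Besides Vim, Twist2 went from 0.457 to 9.98 FPKM, Col5a1 from 0.182 to 2.22 and Sparc from 12.8 to 61.8 in the authors' deposited table. EZH2-repressed growth regulators rose in 7 of 20 and fell in 4 (12 adjusted over the list alone), median 0.14 (adjusted p = 0.00357, and adjusted p = 0.187 on ranks). There Sfrp1 rose from 0.261 to 9.01 FPKM and the inhibitor gene Cdkn1c from 0.323 to 1.83.

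Of 18 Hox genes tested in the knockout, 11 rose and 0 fell (11 adjusted over the list alone), median 1.94. All 11 are listed at 0 in cas9ctrl, such as Hoxb7 (1.19 FPKM in cas9EZH2) and Hoxb3 (2.56), and, chosen after their values were seen, Hoxb9 (27.3) and Hoxb13 (10.2). The list test covers the 6 Hox genes with a finite score and none of those 11 (adjusted p = 0.0244).

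The remaining lists did not pass the list test in the knockout. PRC2 genes had 0 up and 1 down of 11 (1 adjusted over the list alone), median 0.05 (adjusted p = 0.876). The changed one was Ezh1, the paralog of Ezh2, which went from 13.3 to 10.1 FPKM. PRC1 genes had 2 up and 1 down of 19 (3 adjusted over the list alone), median -0.01 (adjusted p = 0.876). Developmental factors outside the Hox clusters had 3 up and 7 down of 26 (11 adjusted over the list alone), median -0.06 (adjusted p = 0.893). Endodermal and pancreatic factors had 6 up and 4 down of 14 (12 adjusted over the list alone), median 0.01 (adjusted p = 0.251). Gata4 rose from 0.397 to 5.44 FPKM and Foxa2 from 2.70 to 7.13, and Foxa3 fell from 5.45 to 1.43. Classical subtype genes had 7 up and 6 down of 17 (15 adjusted over the list alone), median -0.07 (adjusted p = 0.903). Epithelial markers had 2 up and 9 down of 32 (15 adjusted over the list alone), median -0.18 (adjusted p = 0.313), with Cdh1 at 122 and 115 FPKM (q = 0.667 in the authors' deposited table). Ductal markers had 3 up and 4 down of 9 (7 adjusted over the list alone), median 0.03 (adjusted p = 0.246).

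RAS-ERK genes had 2 up and 10 down of 28 (15 adjusted over the list alone), median -0.13 (adjusted p = 0.0969), with Dusp6 down from 239 to 103 FPKM. WNT genes had 7 up and 4 down of 20 (11 adjusted over the list alone), median 0.10 (adjusted p = 0.223). NOTCH genes had 2 up and 6 down of 20 (8 adjusted over the list alone), median 0.07 (adjusted p = 0.718). For p53 targets the counts were 6 up and 2 down of 28 (10 adjusted over the list alone), median 0.13 (adjusted p = 0.116). Cholesterol synthesis had 2 up and 2 down of 23 (4 adjusted over the list alone), median 0.09 (adjusted p = 0.893). NF-kB genes had 2 up and 7 down of 24 (11 adjusted over the list alone), median -0.09 (adjusted p = 0.193), with Ccl5 down from 119 to 10.3 FPKM and Ccl2 up from 5.21 to 32.4. Ribosomal proteins had 0 changed of 52 (0 adjusted over the list alone), median 0.06 (adjusted p = 0.687). Acinar markers had 3 up and 0 down of 15 (3 adjusted over the list alone), median 0.28 (adjusted p = 0.182). Fibroblast and stellate markers had 3 up and 2 down of 7 (5 adjusted over the list alone), median 0.19 (adjusted p = 0.876). Too few were tested for a list test of endocrine markers (1 up of 2, 1 adjusted over the list alone, median 1.15), endothelial markers (1 up and 1 down of 3, 2 adjusted over the list alone, median 0.16), immune markers (3 down of 3, 3 adjusted over the list alone, median -0.70) and germline genes (0 past the threshold of 1, 1 adjusted over the list alone, median 0.30).

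In the knockout, too, parts of the genome stood apart. The Y-linked genes Ddx3y, Uty and Kdm5d, chosen after their values were seen, are listed at 0 in cas9ctrl and at 15.2, 7.51 and 7.28 FPKM in cas9EZH2 in the authors' deposited table. Eif2s3y was at 0.0329 and 40.1 FPKM there (q = 0.471). A stretch of chromosome 18 (mm9, 36459754 to 38477503) had a median log2 fold change of -0.61 over 25 genes, of which 20 fell and 0 rose. Chromosome 19 had a median of -0.05 over 357 genes.

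**Figure D2:**
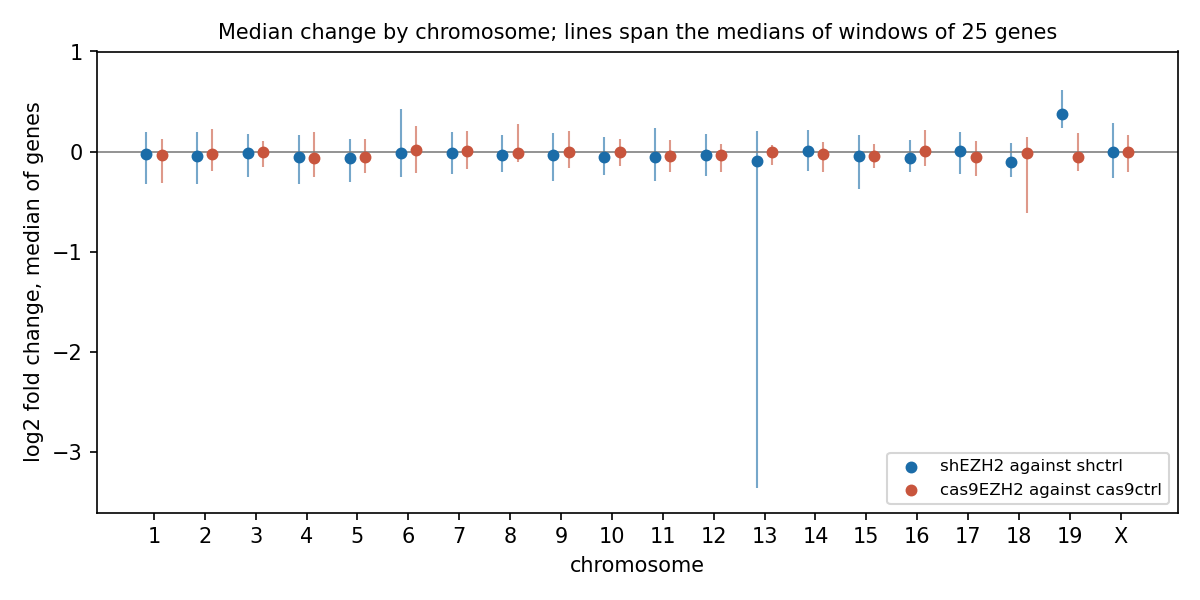
Median log2 fold change per chromosome in the knockdown (blue) and the knockout (red), with lines over the range of medians in windows of 25 neighbouring genes. Chromosome 19 lies at 0.38 in the knockdown, and the lowest window of chromosome 18 lies at -0.61 in the knockout. The lowest window of chromosome 13, at -3.35 in the knockdown, spans the Hist1 genes, whose transcripts mostly lack a poly(A) tail.

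Set side by side, both depletions shared more genes than the margins give, most of all among rises. Of 11122 genes tested in both tables, 428 rose in both (175 from the margins, odds ratio 4.01, Fisher's exact p = 1.7e-84) and 337 fell in both (173, odds ratio 2.66, exact p = 5.6e-39). A further 243 rose in the knockdown and fell in the knockout (168, odds ratio 1.66, exact p = 3.33e-10), and 191 did the reverse (181, odds ratio 1.07, exact p = 0.394). At q under 0.01 in both, the reverse direction also passed its margins, with 120 genes (87.0, odds ratio 1.49, exact p = 0.000201), and 168 rose in the knockdown and fell in the knockout (85.7, odds ratio 2.41, exact p = 1.12e-18). At q under 0.05, 765 of the 1199 genes called in both moved the same way (63.8%). The largest shared rises were of the RNA-binding protein gene Igf2bp3, Galnt18, the Axl ligand gene Gas6 (1.81 to 55.3 and 1.25 to 19.8 FPKM), Spats2l and Cpeb1. Igf2bp3 rose 36.3-fold in the authors' deposited table for the knockdown and 49.7-fold in that for the knockout. The largest shared falls in the authors' deposited tables were of Crip1, the keratin gene Krt20 (21.3 to 3.76 and 28.2 to 2.56 FPKM), Nebl, Id3 and AW011738. Across 11019 genes the log2 fold changes had a Spearman's rho of 0.15 and a Pearson's r of 0.20. Over the 6821 genes at 10 FPKM or more, rho was also 0.15 and r was 0.08.

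The difference test found 816 of 10400 genes whose change differed, 421 higher and 395 lower in the knockdown, and for 595 of them the signs were opposite. With the error taken from p, an alternative chosen after seeing the data, 2089 differed, 1043 higher and 1046 lower, with opposite signs for 1656. Cd34 rose from 9.26 to 263 FPKM in the authors' deposited table for the knockdown and fell in the knockout. Gatm fell from 4.51 to 0.485 FPKM in the knockdown and rose from 3.07 to 21.2 in the knockout, and Agt went from 27.5 to 144 and from 1.76 to 0.136. Of 26 lists tested on the difference, 13 passed, with interferon response (adjusted p = 3.75e-100), class I antigen presentation, p53, ATF4 and NF-kB genes higher in the knockdown. Cell cycle genes (adjusted p = 7.11e-11), epithelial, mesenchymal, fibroblast, hypoxia, endodermal, acinar and TGF-beta lists were lower in the knockdown than in the knockout. At a correlation of 0.05, 9 lists passed, and the endodermal, acinar, TGF-beta and p53 lists did not (adjusted p = 0.0523, adjusted p = 0.137, adjusted p = 0.135 and adjusted p = 0.153).

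The controls themselves lay far apart. Vim was at 1908 FPKM in shctrl and 5.95 in cas9ctrl, Cdh1 at 2.01 and 122, in tables normalized separately. Over the epithelial list the median log2 ratio of cas9ctrl to shctrl was 3.96, over the mesenchymal list -1.42, and over all genes tested in both 0.04. Each depletion was measured from only 1 of these starting states.

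**Figure D3:**
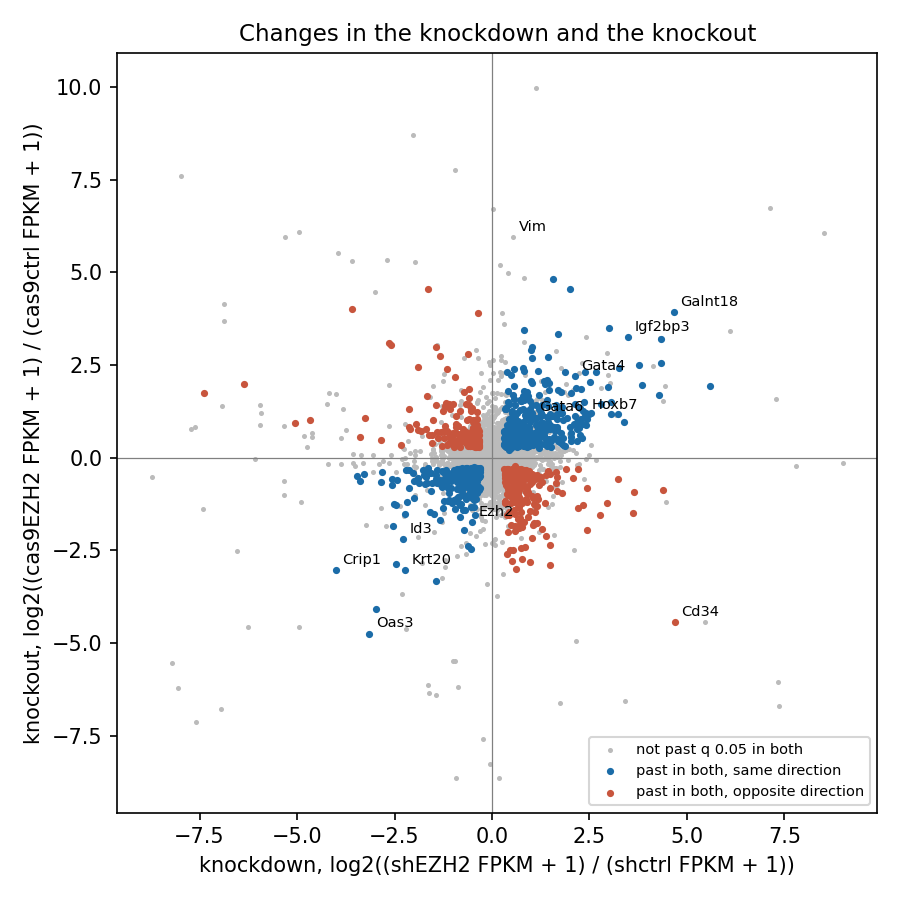
Log2 ratios with a pseudocount of 1 in the knockdown (x axis) and the knockout (y axis), 1 point per gene tested in both. Blue points are the 765 genes past q in both tables with 1 direction, red points the 434 with opposite directions, and grey points all others.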

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

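All tests of explanations in this part were chosen only after the result was seen, and so were the gene groups for small RNAs, histones, Y-linked genes and chromosome 19.

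Small RNAs and histone transcripts without a poly(A) tail were high in shctrl. The median log2 ratio of replication-dependent histone genes differed by -1.83 from that of histone genes with a poly(A) tail. Fewer cells in S phase would lower G1/S genes too. Of 22, 18 had a lower value in shEZH2, with a median log2 ratio of -0.24, against -1.96 for the replication-dependent histone genes. The size of fall to expect in G1/S genes is not known, so fewer cells in S phase stay open as a part of the cause. An effect of EZH2 loss common to both depletions is argued against for the small RNAs, since the 4 that fell and had at least 1 FPKM in cas9ctrl had a median log2 ratio of 1.47 in the knockout, where 2 rose and 0 fell. It stays open for the histone genes, which had a median of only 0.310 FPKM in cas9ctrl and so, for most, little room to fall. Of the 11 replication-dependent histone genes tested in the knockout, 2 fell and 0 rose. RNA without a poly(A) tail carried into the shctrl libraries may account for this group, and its source was not tested.

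Epithelial genes were lower in shEZH2 than in shctrl. An effect of EZH2 loss common to both depletions would lower the markers that fell in the knockout too, where their median log2 ratio was -0.17. Over the whole list, 9 of 32 tested fell and 2 rose there. The list started from a median log2 ratio of cas9ctrl to shctrl of 3.96. An equal fall is thus argued against for these markers, and a smaller common effect stays open. A single small share of cells with the cas9ctrl levels in the shctrl samples is argued against as the whole cause. Over the 9 markers that fell, the excess in shctrl ranged from 1.08% to 27.1% of the cas9ctrl level (Cldn3 the highest), 25.2 times from lowest to highest. As a part of the cause such a share stays open: of 23 markers with at least 20 FPKM in cas9ctrl, 69.6% had an excess within 2-fold of the median of 1.73%, 4 had more and 3 had less.

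Y-linked genes and chromosome 19 were shifted in shEZH2. An effect of EZH2 loss common to both depletions is argued against for the Y-linked genes, as they rose in the knockout from levels near 0, with a median log2 ratio of 3.55 (lowest 3.05), 3 of 4 past the threshold, and for chromosome 19, whose median in the knockout was -0.051. A different share of cells with a Y chromosome in the compared samples may account for the former, since the highest shEZH2 share of the shctrl level was 1.59 times the lowest. A gain of the whole of chromosome 19 in shEZH2 may account for the latter, since its lowest window of 25 genes had a median of 0.23. The ratio of shEZH2 to shctrl cannot tell such a gain from a loss in shctrl. These would be differences between the cell populations, and whether they arose by chance in culture was not tested. Other changes in either comparison cannot be told apart from effects of such differences.

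The change of Ezh2 itself differed between knockdown and knockout (adjusted p = 0.000397), as did that of 816 genes (2089 with the error taken from p). The 5 largest z values of the difference were 18.6 for Cd34, 16.3 for Ptprb, 16.2 for Mir7052, 14.5 for Mme and 14.5 for Col4a2. Mir7052 was not past the threshold in the authors' deposited table for the knockdown (q = 0.751) or the knockout (q = 0.838), so its z rests on a small implied error. Ptprb went from 1.40 to 11.9 FPKM in the knockdown and from 11.8 to 2.30 in the knockout, Mme from 3.70 to 30.8 and from 24.6 to 7.71, and Col4a2 from 3.20 to 31.3 and from 59.3 to 24.7.

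Lists whose change was higher in the knockdown than in the knockout were interferon response (adjusted p = 3.75e-100), class I antigen presentation (adjusted p = 1.78e-16), ATF4 and unfolded protein genes (adjusted p = 0.000239), NF-kB genes (adjusted p = 0.00372) and p53 targets (adjusted p = 0.0362). Lower in the knockdown were the epithelial list (adjusted p = 1.24e-11), the cell cycle list (adjusted p = 7.11e-11), the mesenchymal list (adjusted p = 9.5e-10), the fibroblast and stellate list (adjusted p = 0.000307), the hypoxia list (adjusted p = 0.000307), endodermal and pancreatic factors (adjusted p = 0.0173), TGF-beta targets (adjusted p = 0.0282) and acinar markers (adjusted p = 0.0468). At a correlation of 0.05 the endodermal (adjusted p = 0.0523), TGF-beta (adjusted p = 0.135), acinar (adjusted p = 0.137) and p53 (adjusted p = 0.153) lists lost their calls.

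Rn45s, the ribosomal RNA precursor, had too many reads for a test in the knockdown table and was outside the comparisons. It is listed at 0 in shctrl and at 320.5 FPKM in shEZH2. Given that status, the 0 cannot be read as absence from shctrl, and no direction is drawn from these values.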

How the results depend on the processing

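Alternatives that leave out chromosomes or RNA kinds, that take the error from p, or that change the difference tests were chosen after seeing the data. No result reversed its direction under the alternatives run. The counts of changed genes (3381 in the knockdown, 2851 in the knockout) stayed within 1.5-fold under q below 0.01 (2401 and 2048), without merged entries (3378 and 2850), without RNA lacking a poly(A) tail (3349 and 2844), without chromosomes 19 and Y (3172) and without the chromosome 18 stretch and Y (2827). With a 2-fold minimum they were 997 and 806, by construction fewer. By Bonferroni they were 0 and 0, since the smallest p of 5e-05 cannot pass over so many tests. With a normal p of the centred test statistic they were 1186 and 1355. These leave out tested genes listed at 0 in a group. Over the same genes the authors' p, adjusted again, called 3331 and 2796, and the normal p without centring 1176 and 1362, so the kind of p and not the centring or the genes left out lowers them. The filters at 1 FPKM removed no tested gene and are void. With a pseudocount of 1 the log2 ratios of Gata6 were 1.04 and 1.09, since its levels are near 1 FPKM. Of the 249 changes of other named genes, 126 moved by more than their implied error with a pseudocount of 1 and 0 reversed, and none moved with centring. The medians used for centring were only -0.0170 in the knockdown and -0.0167 in the knockout, small beside the median implied errors, so centring could hardly move a gene. The number of lists called in the knockdown (11) became 6 at a correlation of 0.05 and 6 on log2 ratios with a pseudocount, and the cause was not tested. Against random lists it was 18, and on ranks 11. For the knockout (10) the numbers in this order were 9, 7, 13 and 12. The count against random lists is another kind of call. It takes list medians past the outer percentiles of random lists, unadjusted over lists, and includes genes listed at 0. Of 34 list calls (21 within a comparison, 13 of the difference), 10 were lost at a correlation of 0.05 and 6 on ranks, and of the 21, 9 were lost on log2 ratios and 4 against random lists. Those 4 were the ductal and NOTCH lists in the knockdown and the EZH2-repressed growth regulators in both comparisons. Called lists had 1 sign in median, mean and test. Among lists not called, these differed in sign for hypoxia in the knockdown and for PRC1, developmental factors, classical genes and NOTCH in the knockout. Genes changed alike in both tables (765) were 480 at q below 0.01, with fewer genes called. Genes that fell in the knockdown and rose in the knockout did not exceed the margins at q below 0.05 (odds ratio 1.07, exact p = 0.394) but did at 0.01 (odds ratio 1.49, exact p = 0.000201). Genes whose change differs (816) were 2089 with the error taken from p. No paired analysis was possible because the tables hold a single value per group, so a replicate block, leave-one-out and other splits of the samples could not be run either. The depth of the samples is not known, and what it limits cannot be given.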

Other observations

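Neighbouring Oas genes of chromosome 5 fell in the knockdown, where 28 of 46 interferon genes rose, 5 fell and 13 did not pass the threshold, a pattern noticed after the values were seen. Oas2, Oas3, Oas1b, Oas1g and Oas1a lie together at mm9 121180341 to 121357534. In the authors' deposited table for the knockdown Oas1b also fell, from 9.55 to 2.87 FPKM, while Oas1g was at 2.77 and 0.0840 FPKM (q = 0.406). In the knockout Oas1b fell from 15.7 to 0.660 FPKM, and Oas1g, at 6.23 FPKM in cas9ctrl, is listed at 0 in cas9EZH2. Neighbours on either side did not pass the threshold: Ddx54 was at 30.1 and 29.3 FPKM in the knockdown and at 39.0 and 34.5 in the knockout, and Ptpn11 at 55.7 and 53.4 and at 48.7 and 47.9.

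The chromosome 18 stretch that fell in the knockout had a median log2 fold change of -0.11 in the knockdown, where 6 of its 25 genes fell and 0 rose. The lowest window elsewhere in the knockout was on chromosome 1 (173259275 to 177622763), at -0.31. In the stretch, Hars went from 61.9 to 37.1 FPKM and Diap1 from 42.5 to 24.1 in the authors' deposited table for the knockout, both chosen after their values were seen.

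Set against shctrl, in tables normalized separately, the interferon list had a median log2 ratio of 0.41 in cas9ctrl, 0.49 in shEZH2 and -1.16 in cas9EZH2. The cell cycle list lay at -1.004 in cas9ctrl, -0.26 in shEZH2 and -0.51 in cas9EZH2.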
